A study of Homo sapiens with 2 samples.

How the data were processed

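Total RNA from NT2 cells was measured on 2 Affymetrix HG-U133A oligonucleotide arrays, 1 from cells kept for 48 hours with the solvent DMSO and 1 from cells kept for 48 hours with 10 µM retinoic acid (RA). NT2 (NTERA-2) is an established human embryonal carcinoma cell line, a pluripotent tumour line widely used as a model of retinoid-driven neural differentiation. Per the labels, RNA was converted to biotin-labelled cRNA by in vitro transcription and hybridised to the chip. Each array measured a single sample in 1 colour, and groups were taken from the sample titles.

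The deposited values are signal intensities per probe set on a linear scale. Per the labels, the authors made them with RMA in the Gene Traffic software, which background-corrected and normalised the arrays. The software version and the chip definition file are not given in the sources used here. The table holds whole numbers from 9 to 16712, and the lower quartile was 42 on both arrays, so the values were read as RMA output returned from the log scale and rounded. The labels also name a filter for a signal of 50 or more in at least 1 comparison. It had not been applied to the table, since 6267 of its 22283 probe sets lay below 50 on both arrays. RMA uses the perfect-match probes alone, which compresses differences at low signal, and the table carries no detection call, so the threshold of 50 was used as the limit of measurement. Of the 27 probe sets for Bacillus transcripts, 1 reached 50, and their median was 16 on the DMSO array and 17 on the RA array.

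Probe sets were named from the platform annotation supplied with the table, with symbols looked up by gene identifier in RefSeq's gene table for GRCh38.p14. In all, 19065 probe sets carried 1 gene symbol, 1043 carried several and 2107 carried none. The last of these are unnamed here and not without a gene. The remaining 68 were control probe sets. A gene identifier was found in the RefSeq table for 19059 of the probe sets with 1 symbol, and the lookup changed 0 symbols. No coordinates are given, because the array annotation names no build, and the RefSeq table was used for names and for which genes neighbour each other. The 11963 genes with a probe set of their own were each represented by the probe set with the highest mean log2 signal, and 9487 of them had a signal of 50 or more on at least 1 array.

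The difference was computed as the log2 signal on the RA array minus that on the DMSO array, with no further scaling. With 1 array per condition there is no replicate, so there is no test, p-value or standard error. Genes are described by a fixed rule of size, a difference of at least 2-fold, and "higher" and "lower" compare these 2 arrays. The number of arrays limits the precision. Where the dimmer array was below 50, the fold is given as a lower bound, the brighter signal over 50, while counts of genes and list medians use the measured signals. The 28 gene lists were fixed before the data were examined and hold 805 genes, of which 674 had a probe set of their own and 572 reached the threshold. Each list's median log2 difference was placed among the medians of 10000 random lists of the same size, drawn from genes outside the list and matched on mean signal in 20 bins. That percentile describes these 2 arrays. Of the 28 lists, 7 lay outside the central 95% of their random lists. The 1.4 expected by chance holds only for members that vary independently, as in the random lists. Genes of a real list can vary together, so 7 against 1.4 is no test. The reference genes, a control list, were among the 7.

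Genes were named by a rule also fixed before the data were examined. It takes the 15 genes with the highest and the 15 with the lowest log2 difference whose probe sets at 50 or more all differed in the same direction, the 2 highest and 2 lowest members of each list, any member of lists of up to 15 genes, and a short set of retinoid, pluripotency, neural and control genes. Genes that complete a count of 5 or fewer and fall outside the rule were named after their values were seen. These are NRIP1, DLX5, ISL1, GBX2, NCAM1, FZD7, FZD10, SFRP1, FLRT2, FLRT3 and ETV4. DHRS3, STRA6, RARA, RARG, RXRA, HOXC6, SPRY1, ETV5, DUSP4, DNMT3B, CER1, the measured neighbours of HOX clusters, the POU5F1-like genes, the genes of added families and adjacent pairs were also chosen after their values were seen.

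The procedure was tested on simulated data for the RA against DMSO comparison, with noise set to the robust SD of the real differences, 0.21 on the log2 scale. Among 9493 genes, 99.0% of 200 genes changed 3-fold were counted as at least 2-fold different, and 0 unchanged genes were counted. Among 9478 genes, 6.0% of 200 genes changed 1.5-fold were counted. Of 200 unchanged lists, 196 lay inside the central 95% of random lists in the 3-fold simulation and 188 in the 1.5-fold simulation, which drew fewer random lists than the data. The simulated noise has the same SD at every signal and holds no difference between cultures. It was small beside the 2-fold limit, so the 0 unchanged genes counted follow from this setting. They do not measure the error of the real counts. Alternatives covered 3 scalings of the arrays, of which median centring changed no gene value because the median difference was 0, the signal threshold, an offset before the logarithm, the choice of probe set and the size threshold. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 (lowess) and matplotlib 3.10.9 were used.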

Results

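Gene expression was compared in NT2 human embryonal carcinoma cells after 48 hours with DMSO, the solvent control, or with 10 µM RA, the vitamin A derivative that acts through nuclear retinoic acid receptors. There was 1 array per condition and therefore no replicate, so each value below is a single measurement and none of the differences has a replicate check. The median signal over 22283 probe sets was 87 on the DMSO array and 88 on the RA array. A signal of 50 or more was reached by 70.1% of probe sets on the DMSO array and by 69.8% on the RA array. Log2 signals correlated across probe sets with Pearson's r = 0.98, where probe sets are not independent replicates. The signal of ACTB probes at the 3′ end over that at the 5′ end, a sign of RNA integrity, was 0.721 with DMSO and 0.714 with RA, and the same ratio for GAPDH was 0.946 and 0.986. The 18 control probe sets for bacterial and phage transcripts differed between arrays by a median of 0.12 on the log2 scale, from -0.13 to 0.38.

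The comparison of RA with DMSO asks which genes differ after 2 days of retinoid exposure. The adaptor SKAP2, the homeobox genes MEIS2 and PAX6 and the retinoid genes CRABP2 and CYP26A1 were among the 15 highest genes on the RA array by measured signal, and NANOG, CD9 and L1TD1 were the 3 lowest. Of 9487 genes, 148 were at least 2-fold higher and 72 at least 2-fold lower on the RA array by measured signal, and for 14 and 2 of these the bound at 50 lay under 2-fold. The 148 and 72 were 1.56% and 0.76% of the genes, 2.32% together, the shares beside which counts within lists are to be read. At 4-fold, 39 were higher and 10 lower, and at 8-fold, 11 were higher and 2 lower. The central 95% of genes lay between -0.57 and 0.76 on the log2 scale, and the median gene did not differ (0.00). Among the 148 higher genes, 48 had a further probe set at 50 or more, and 71 of those 74 further probe sets were also higher, 46 of them at least 2-fold. Among the 72 lower genes, 25 of 27 further probe sets were also lower, 13 of them at least 2-fold. The counts were 89 and 37 with 50 added to each signal before the logarithm, and 135 and 70 with signals below 50 set to 50.

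**Figure D1:**
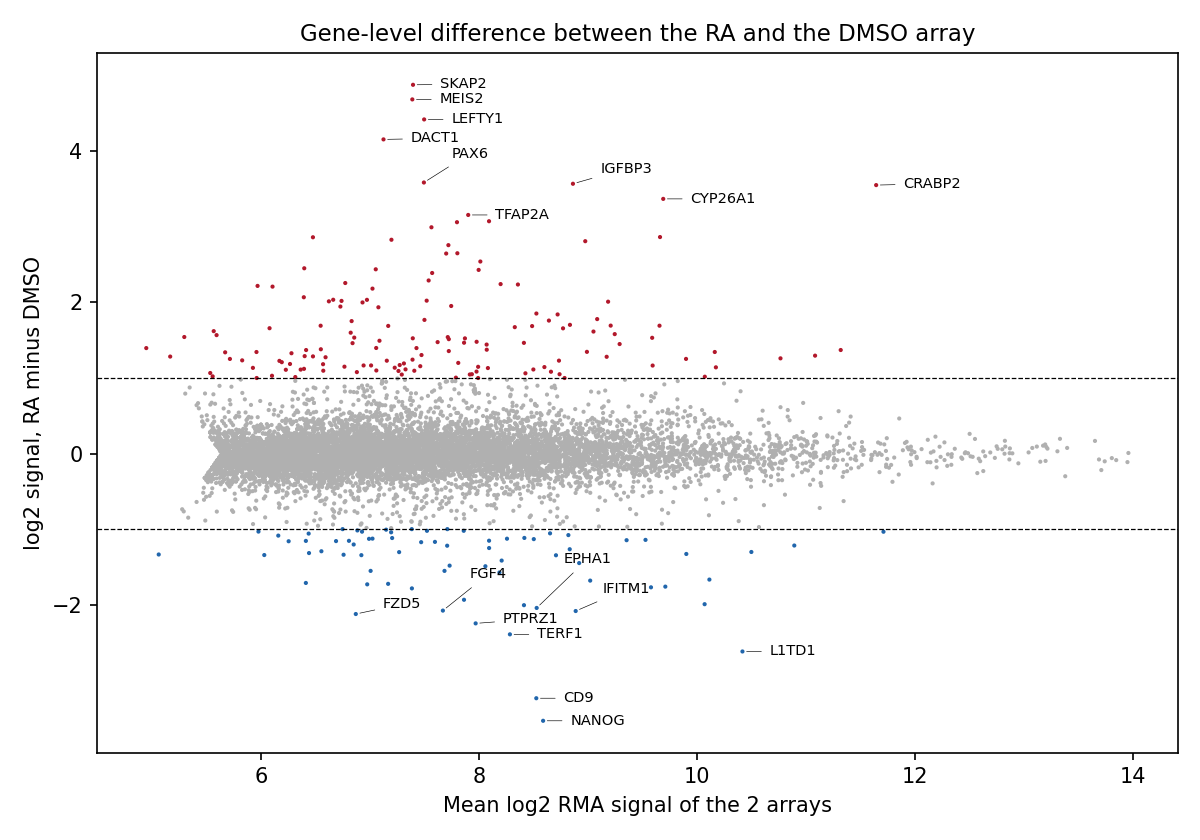
Log2 signal on the RA array minus that on the DMSO array (vertical axis) against the mean log2 RMA signal of both arrays (horizontal axis) for 9487 genes, 1 point per gene, with 1 array per condition. Dashed lines mark 2-fold; the 148 higher genes are red, the 72 lower genes are blue, and the 9 highest and 9 lowest genes are labelled.

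SKAP2, a src-kinase-associated adaptor protein, was at 31 with DMSO and 913 with RA, at least 18.3-fold higher. Of its other 3 probe sets, 2 were also higher, at 21 and 26 with DMSO and 551 and 991 with RA, and the remaining one was near equal at 79 and 83. MEIS2, a TALE homeobox factor, was at least 17.0-fold higher, and LEFTY1, a secreted antagonist of Nodal, at least 16.7-fold higher. The order of these 3 genes is not measured, since each lay below 50 with DMSO. DACT1, a regulator of WNT signalling that binds Dishevelled, was at least 11.8-fold higher. PAX6, a regulator of neural and eye development, had a log2 difference of 3.59, from 52 to 625. IGFBP3, a binding protein of insulin-like growth factors, was 11.9-fold higher, with a second probe set at a log2 difference of 3.15. The ectodermal transcription factor TFAP2A was 8.93-fold higher, with a second probe set at 22 and 104, LAMP5 8.43-fold, the HMG-box factor SOX3 7.97-fold and the small GTPase RHOB 7.29-fold. PLAGL1, an imprinted zinc finger gene, was 7.11-fold higher by its brightest probe set and 3.57-fold and 3.03-fold higher by 2 others. GATA3 was 8.35-fold higher by its brightest probe set and 2.02-fold higher by its other probe set at 50 or more.

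Among genes whose probe sets at 50 or more all differed in the same direction, the lowest on the RA array were the pluripotency factor NANOG (11.6-fold lower), the tetraspanin CD9 (9.43-fold), the stem-cell RNA-binding protein L1TD1 (6.14-fold) and the telomere-binding protein TERF1 (5.25-fold). They were followed by PTPRZ1, a receptor phosphatase, at 4.75-fold lower, and by the WNT receptor FZD5 at 4.36-fold lower, with a second probe set of FZD5 at 70 and 47, under 2-fold. The membrane protein IFITM1 was 4.24-fold lower, the growth factor FGF4 4.22-fold, the Eph receptor EPHA1 4.12-fold and TMEM158 4.02-fold. The Polycomb protein PHC1 was 3.98-fold lower, the metalloproteinase inhibitor TIMP4 3.82-fold, and the pro-apoptotic gene PMAIP1 3.41-fold. SEPHS1, of selenium metabolism, was 3.39-fold lower and BRINP1 3.32-fold. Except for FZD5, every one of these 15 genes that had more than 1 probe set at 50 or more, namely TERF1, PMAIP1 and SEPHS1, was at least 2-fold lower by each.

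**Figure D2:**
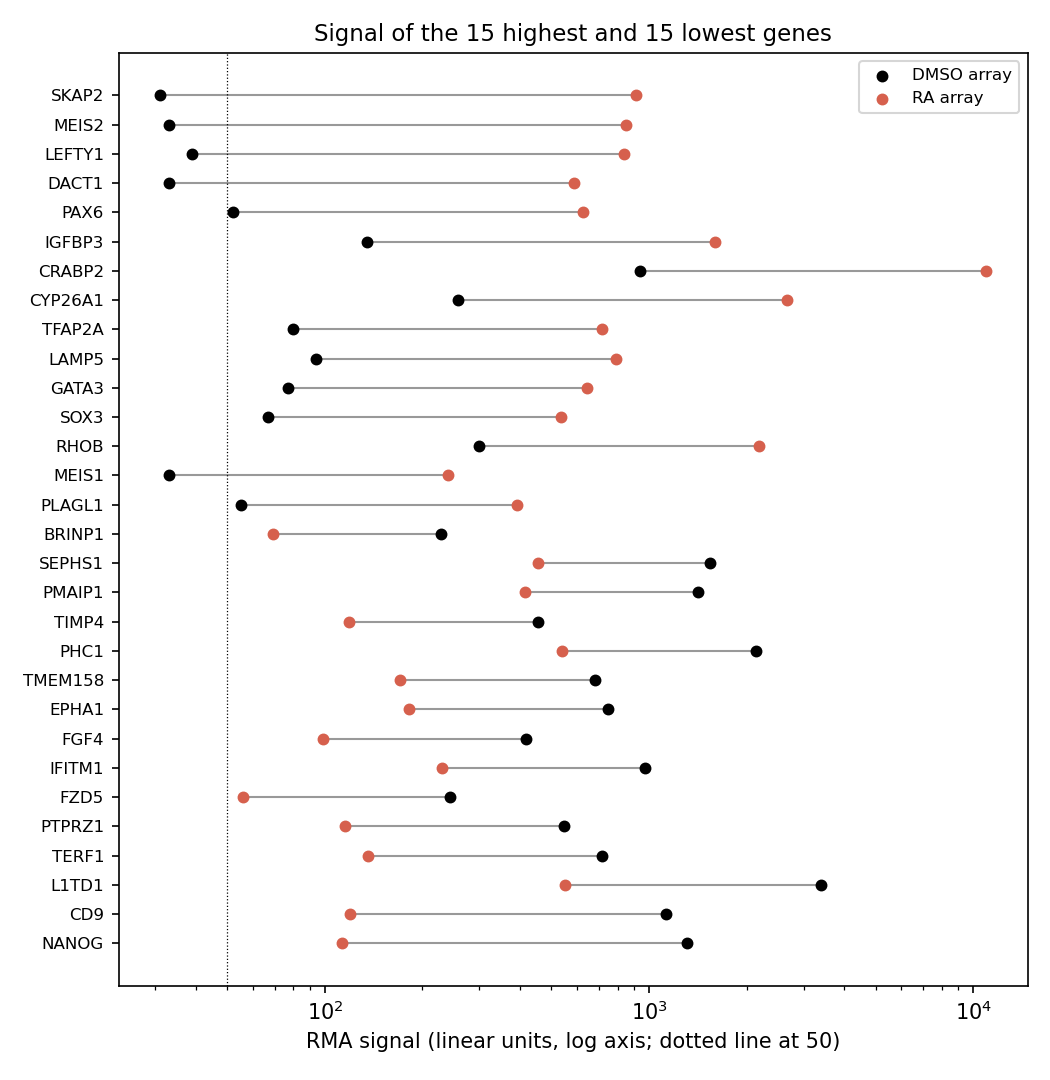
RMA signal (horizontal log axis, linear signal units) of the 15 highest and 15 lowest genes on the DMSO array (black points) and on the RA array (red points), 1 array each, with a line joining the 2 values of a gene and a dotted line at 50. SKAP2, MEIS2, LEFTY1, DACT1 and MEIS1 lay below 50 with DMSO, and CRABP2 reached 10974 with RA.

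Of 23 measured retinoid genes, 4 were at least 2-fold higher on the RA array, beside 1.56% of all 9487 genes. The list median lay inside the central 95% of its random lists. CRABP2, which carries retinoic acid in the cytoplasm, was 11.7-fold higher, from 935 to 10974, and CYP26A1, which degrades retinoic acid, was 10.3-fold higher, from 257 to 2658. RARB, the retinoic acid receptor beta, was 4.10-fold higher by its brightest probe set, and its other 3 probe sets at 50 or more were at 57 and 145, 39 and 52, and 86 and 87. The mean over RARB probe sets was 0.95, just under 2-fold. NRIP1, a nuclear receptor corepressor, was 2.12-fold higher, and DHRS3 and STRA6 had log2 differences of 0.99 and 0.78. LRAT, which esterifies retinol, went from 90 to 44, which with the limit of 50 is at least 1.80-fold lower, and RARRES2 had a log2 difference of -0.37. By measured signal LRAT was the 1 member counted as 2-fold lower, and 18 members lay between. The receptors RARA, RARG and RXRA had log2 differences of 0.08, 0.08 and 0.09. The list's median of 0.08 lay at percentile 96.5, and with 50 added to each signal it was 0.07 at percentile 97.8, above the central 95%.

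Among HOX genes, 2 of 8 measured in paralog groups 1 to 5 and 0 of 5 in groups 6 to 13 were at least 2-fold higher on the RA array, as were 3 of 6 cofactors. HOXD1 was 5.39-fold higher and HOXB2 2.79-fold higher. HOXA2 (30 and 55) was at least 1.10-fold higher, HOXB1 (118 and 159) had a log2 difference of 0.43, and those of HOXD4, HOXC4, HOXB5 and HOXC5 were 0.38, 0.27, 0.03 and -0.19. The median of 0.40 lay at percentile 99.97. Among the cofactors, MEIS2, MEIS1 (at least 4.80-fold) and PKNOX2 (2.86-fold) were higher, while PBX3, PKNOX1 and PBX2 had log2 differences of 0.04, 0.02 and -0.15. The probe sets of PKNOX2 disagreed, from a log2 difference of -0.23 to at least 3.62-fold higher. The cofactor median of 0.78 exceeded all 10000 random lists. In groups 6 to 13, HOXC11, HOXC8, HOXC6 and HOXD9 had log2 differences of 0.10, 0.09, 0.08 and -0.31, HOXB7 was at 53 and 49, and the median of 0.08 lay at percentile 86.9. The difference between the anterior and posterior lists was not tested.

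Of 26 measured genes of the pluripotency list, 11 were at least 2-fold lower on the RA array, 1 was at least 2-fold higher and 14 lay between. Values below 0 of any size numbered 21, and the median of -0.95 lay below all 10000 random lists. NANOG, CD9, L1TD1, TERF1, FGF4 and PHC1 were the 6 lowest. The de novo DNA methyltransferase DNMT3B went from 2129 to 1085, a log2 difference of -0.97. SOX2 went from 780 to 602, a log2 difference of -0.37, and its other 2 probe sets gave -0.08 and 0.03. LIN28A, an RNA-binding protein that blocks let-7 maturation, was at 2340 with DMSO and 3108 with RA, a log2 difference of 0.41. LEFTY1 was the member past 2-fold in the other direction. POU5F1 and TDGF1 had no probe set annotated to them alone and are given no value. Probe sets annotated to the POU5F1-like genes POU5F1B, POU5F1P3 and POU5F1P4 were 2.05-fold, 2.47-fold and 2.32-fold lower. They are uncertain as to gene, since these copies share most of their sequence with POU5F1.

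**Figure D3:**
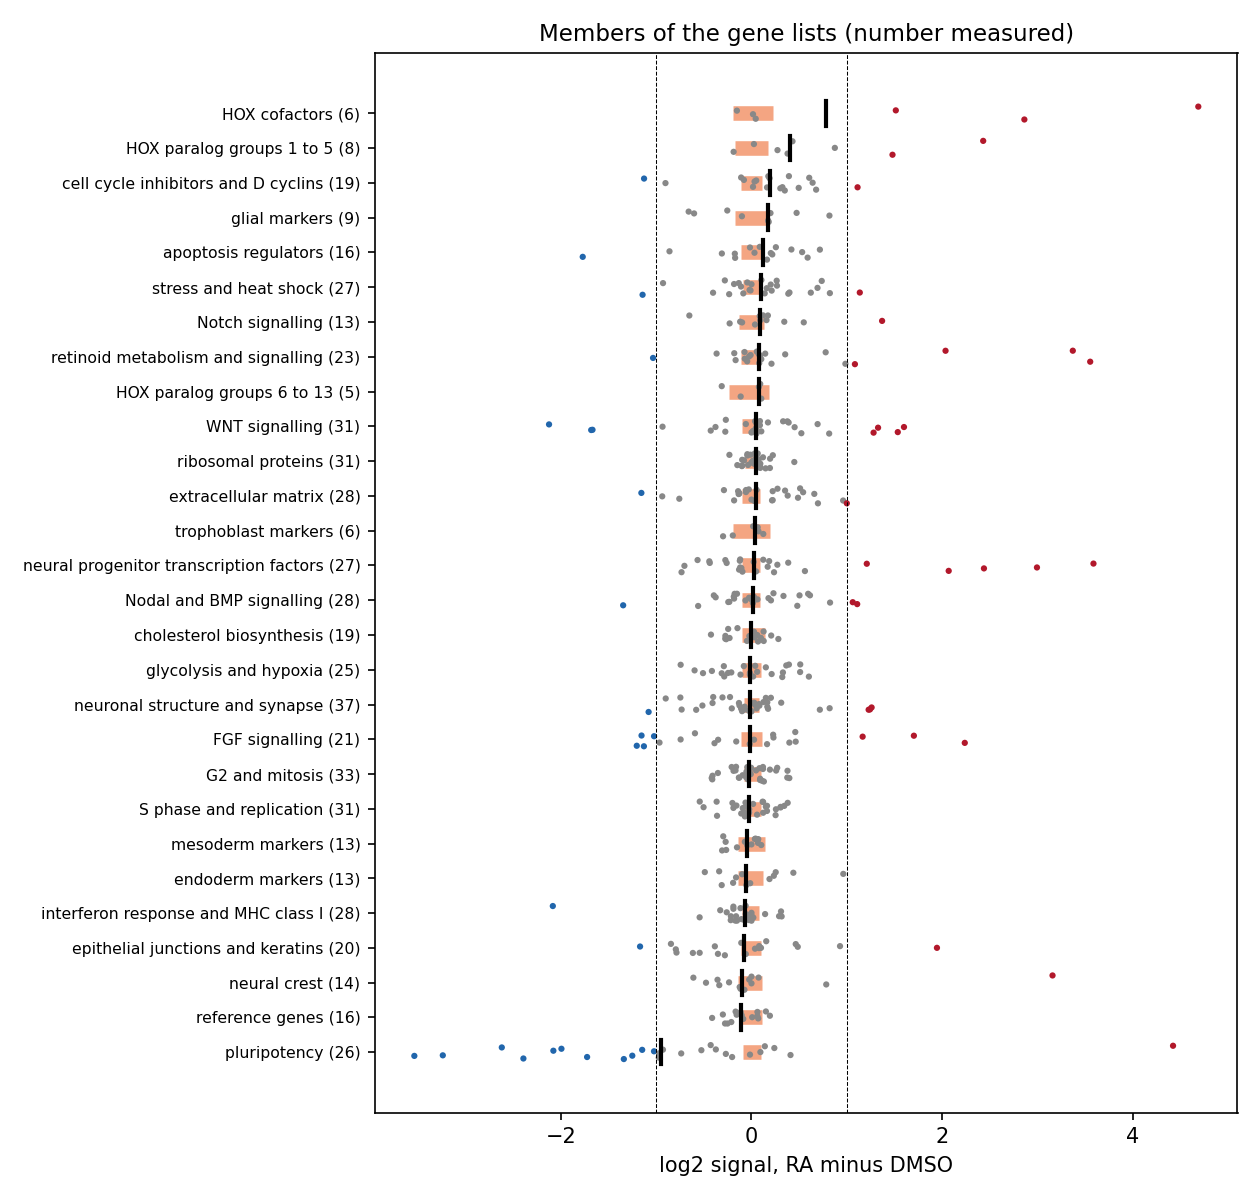
Log2 signal on the RA array minus that on the DMSO array (horizontal axis) for the members of the 28 gene lists (vertical axis, number of measured members in brackets), 1 point per gene and 1 array per condition. Black bars are list medians, orange bands the central 95% of medians of 10000 matched random lists, and dashed lines 2-fold; the pluripotency median of -0.95 and the HOX cofactor median of 0.78 lie outside their bands.

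PAX6 and SOX3, from the list of neural progenitor transcription factors, were among the 15 highest genes by measured signal. Most of that list and most neuronal genes, like most of all genes, did not reach 2-fold. PAX6 and SOX3 were joined by DLX5 (5.42-fold), the LIM-homeobox factor ISL1 (at least 3.44-fold) and GBX2 (at least 2.22-fold). These 5 of 27 measured members were at least 2-fold higher, beside 1.56% of all 9487 genes, and 0 were at least 2-fold lower. The lowest were ID2 at -0.73 and ID4 at -0.70. The list median, which does not register a change in a minority of members, was 0.02, at percentile 73.1. Among 37 neuronal structure and synapse genes, the intermediate filament genes NES (2.40-fold) and NEFM (2.37-fold) and the adhesion molecule NCAM1 (2.34-fold) were higher, though the mean over NCAM1 probe sets was 0.46, while DCLK1 was 2.11-fold lower and DPYSL3 had a log2 difference of -0.90. Their median was -0.02, at percentile 32.9. NR2F1 was below 50 on both arrays, at 17 and 19. Of 14 neural crest genes, TFAP2A was at least 2-fold higher, TWIST1 (36 and 62) was at least 1.24-fold higher, ERBB3 and B3GAT1 had log2 differences of -0.61 and -0.48, and the median was -0.09, at percentile 11.4, or -0.24 at percentile 1.34 with a threshold of 100. Of 9 glial markers, 0 passed 2-fold. FABP7 of radial glia was highest at 0.82 and PDGFRA lowest at -0.66. The glial median of 0.17 lay at percentile 98.6, above the central 95% in 4 of 10 settings, where median centring repeats the main values. It was -0.10 when 13 members were taken without a signal threshold, and 0.03, at percentile 70.2, with signals below 50 set to 50.

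By the probe set representing each gene, none of the mesoderm, endoderm and trophoblast markers reached 2-fold, while a second probe set of the endoderm marker CXCR4 was 2.25-fold higher. Since 2.32% of all 9487 genes passed 2-fold, 0 among so few markers is near that share. Many of these markers were dim on both arrays, such as TCF15 (79 and 83), CER1 (55 and 53) and CGA (57 and 60). Others, such as SPARC (958 and 1299) and TEAD4 (418 and 340), were brighter. The highest signal of a Bacillus control probe set was 89, so the dim signals do not show that a marker was expressed. The 13 mesoderm markers had a median of -0.04 at percentile 31.1, with PECAM1 and TCF15 highest at 0.10 and 0.07 and HAND2 (52 and 42) and HAND1 (log2 difference -0.30) lowest. The 13 endoderm markers had a median of -0.05 at percentile 27.8, with CXCR4, a chemokine receptor, highest at 0.96, SPARC at 0.44, and FOXA2 and LAMB1 lowest at -0.49 and -0.34. The 6 trophoblast markers had a median of 0.04 at percentile 68.0, between PSG1 at 0.12, CGA at 0.07, PSG4 at -0.20 and TEAD4 at -0.30. Among 20 genes of epithelial junctions and keratins, the desmosomal PKP2 was 3.85-fold higher and the adhesion molecule EPCAM 2.25-fold lower. KRT8 had a log2 difference of 0.93, DSP (88 and 49) was at least 1.76-fold lower, and the median was -0.08 at percentile 6.30. Among 28 extracellular matrix genes, COL18A1 went from 312 to 624 (log2 difference 0.94 after quantile normalisation), POSTN had a log2 difference of 0.96, COL6A2 was 2.23-fold lower and TNC had -0.94. The mean over COL6A2 probe sets was -0.69, its value without shared-sequence probe sets was -0.22 (70 and 60), and the list median was 0.04 at percentile 83.4, or 0.09 at percentile 98.4 with means over probe sets.

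Signalling genes differed in both directions. Of 31 WNT genes, the receptors FZD6 (3.03-fold), FZD10 (at least 2.46-fold) and FZD7 (2.43-fold) and the secreted antagonist FRZB (2.90-fold) were higher, with second probe sets of FZD7 and FRZB at 1.97-fold and 1.77-fold. FZD5, the transcription factor TCF7L1 (3.21-fold) and the secreted antagonist SFRP1 (3.18-fold) were lower, though FZD5 had -0.57 without shared-sequence probe sets. Of 21 FGF genes, the MAP kinase phosphatase DUSP6 (3.26-fold), SPRED2 (4.72-fold, or 2.27-fold by a second probe set) and FLRT3 (2.24-fold) were higher, and SPRY2 (2.30-fold), SPRY4 (2.22-fold), FLRT2 (2.19-fold) and the ETS factor ETV4 (2.03-fold) were lower, with a mean over FLRT2 probe sets of -0.85. Of 28 Nodal and BMP genes, GDF15 (2.16-fold) and SKIL (2.09-fold) were higher, the homeobox repressor TGIF1 was 2.54-fold lower, and SMAD7 had a log2 difference of -0.56. Of 13 Notch genes, HEY2 was 2.58-fold higher, NOTCH2 had a log2 difference of 0.55, and RBPJ and MAML1 had -0.65 and -0.23. The medians of the WNT, FGF, Nodal and BMP, and Notch lists were 0.05, -0.02, 0.02 and 0.09, at percentiles 91.1, 38.7, 74.5 and 91.9. With a threshold of 100 the first 3 became 0.21, -0.35 and 0.18, each outside the central 95% of random lists, as were the WNT median of 0.09 with means over probe sets and the FGF median of -0.16 without a threshold.

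Proliferation genes stayed near 0. None of 31 S phase genes and none of 33 G2 and mitosis genes reached 2-fold, which is near the share of 2.32% among all 9487 genes. The medians of these lists were -0.02 and -0.02, at percentiles 24.5 and 25.6. The extremes were GINS2 and GMNN at 0.38 and 0.34 against MCM5 and TK1 at -0.54 and -0.50 in S phase, and CENPF and PRC1 at 0.40 and 0.38 against CDC20 and DLGAP5 at -0.42 and -0.41 in mitosis. Cell cycle inhibitors and D cyclins had a median of 0.19 over 19 genes, at percentile 99.9. In that list the stress-inducible GADD45A was 2.16-fold higher and GADD45G had a log2 difference of 0.68, whereas cyclin D1 (CCND1) was 2.18-fold lower by its brightest probe set and 1.75-fold lower by the other, a mean of -0.97, and MYC had -0.90. Of 16 apoptosis regulators, PMAIP1 was at least 2-fold lower and BIK had a log2 difference of -0.86, while FAS was at 45 with DMSO and 74 with RA and TNFRSF10B had 0.59. Their median of 0.12 was opposite in sign to the mean of -0.01, and it lay at percentile 97.1. It passed the central 95% after quantile normalisation (percentile 98.1) and without shared-sequence probe sets (0.22, percentile 99.8).

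The remaining lists held few differences. Of 28 interferon response and MHC class I genes, IFITM1 was at least 2-fold lower, IFITM3 had a log2 difference of -0.54, and BST2 and UBE2L6 had 0.32 and 0.31, with a median of -0.07 at percentile 9.03. The 19 cholesterol biosynthesis genes ranged from SQLE at -0.42 and LSS at -0.28 to HSD17B7 at 0.21 and MSMO1 at 0.28, with a median of -0.01 at percentile 34.6. The 25 glycolysis and hypoxia genes ranged from the glucose transporter SLC2A3 at -0.74 and ALDOC at -0.60 to P4HA1 at 0.51 and SLC2A1 at 0.60, with a median of -0.02 at percentile 35.1. Of 27 stress genes, VLDLR was 2.20-fold higher, the cystine transporter SLC7A11 had 0.82, the metallothionein MT1X was 2.21-fold lower and MT2A had -0.93, with a median of 0.10 at percentile 99.0, or 0.04 at percentile 80.6 with means over probe sets. The 31 ribosomal protein genes ranged from RPL24 at -0.23 and RPL8 at -0.15 to RPL6 at 0.22 and RPS25 at 0.45, with a median of 0.05 at percentile 94.4. The 16 reference genes had a median of -0.11 at percentile 1.82, between TFRC at -0.41, PPIA at -0.30, YWHAZ at 0.15 and GUSB at 0.19, with GAPDH at -0.11 and ACTB at -0.10. After quantile normalisation the reference median was -0.01, at percentile 53.8, and the differences of GAPDH and ACTB were 0.00.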

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

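Probe sets that carry several gene symbols or none took no part in the comparisons by gene. Of the 1948 such probe sets with a signal of 50 or more on at least 1 array, 17 were at least 2-fold higher on the RA array than on the DMSO array and 6 were at least 2-fold lower. They were picked out as signal in data that the comparisons did not use, and they are not assigned to genes here.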

How the results depend on the processing

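The counts of 148 higher and 72 lower genes moved most with the size threshold and the offset. They were 347 and 226 at 1.5-fold, 60 and 20 at 3-fold, and 89 and 37 with 50 added to each signal before log2, which by construction shrinks differences of dim genes. Under the other 7 settings chosen beforehand they lay between 134 and 150 and between 66 and 78, and with signals below 50 set to 50, an alternative chosen after seeing the data, they were 135 and 70. Quantile normalisation moved the median of all genes by -0.03 and kept 141 of the 148 and 72 of the 72. Median centring moved no value, and under the other 2 scalings each list median moved by less than the spread of its random lists. With a threshold of 100, which tests fewer genes, they moved for HOX cofactors (1.51), neural crest (-0.24, below the central 95%), epithelial junctions and keratins (0.0370), Nodal and BMP (0.18), WNT (0.21), FGF (-0.35) and the mixed list of cell cycle inhibitors and D cyclins (0.30). Without a threshold they moved for pluripotency (-0.83), FGF (-0.16) and apoptosis (-0.0158), and the glial median turned to -0.10, as dimmer members enter. The pluripotency median was -0.69 with the offset and -0.81 with the mean over probe sets. It was below all random lists in each of 10 settings, of which median centring repeats the main one. The HOX groups 1 to 5, the HOX cofactors and the list of cell cycle inhibitors and D cyclins stayed above the central 95% in all 10, the stress list in 8, the glial list in 4, and the reference genes below it in 6, at percentile 53.8 after quantile normalisation. HOX groups 6 to 13 had too few genes for a value at a threshold of 100. Of 144 named genes, 50 moved by more than 0.21 with the offset, 16 with the mean over probe sets and 11 of 134 without shared-sequence probe sets, and 0 that had passed 2-fold changed sign. With the offset NRIP1, GBX2, NEFM, NCAM1, DCLK1, EPCAM, COL18A1, COL6A2, FZD10, FLRT2, FLRT3, SPRY2, SPRY4, ETV4, GDF15, SKIL, HEY2, GADD45A, CCND1, VLDLR, LRAT, EPHA2, EPHB6, MT1E, NFE2L3, ANXA1 and ANXA9 no longer reached 2-fold. MT1E, NFE2L3, ANXA1 and ANXA9 were not followed in the other settings. Among the remaining genes, 2-fold was also no longer reached by CCND1, COL18A1, COL6A2, FLRT2, NCAM1 and RARB with the mean over probe sets, by COL18A1 and EPHA2 under the 2 scalings that moved values, by COL6A2 (-0.22) and FZD5 (-0.57) without shared-sequence probe sets, and by LRAT with signals below 50 set to 50. For the other lists and settings, where the medians moved, the cause was not tested. Signal near background limits the folds of genes that were dim on an array, and 1 array per condition limits every difference. No paired analysis was possible because each condition has 1 array.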

Other observations

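The tests on gene families, swapped labels, uniform loss of cells and probe sets of SKAP2, DUSP6 and SPRED2 were chosen after the gene values had been seen, while the scalings of the pluripotency list were planned and were read as a test of this pattern afterwards. Percentiles of the families among random lists are therefore not independent evidence. Of 9 Frizzled receptors, 7 lay above 0, 3 of them at least 2-fold higher, and the median log2 difference was 0.69, above all 10000 random lists, although FZD5 was among the 15 lowest genes by its brightest probe set. Of 9 annexins, calcium-dependent membrane-binding proteins, 7 lay above 0 with a median of 0.54, and the 2 past 2-fold by measured signal, ANXA9 (39 and 99) and ANXA1 (34 and 81), were below 50 with DMSO, so that neither is known to reach it. All 6 metallothioneins, which bind zinc and copper, lay below 0, from -1.14 for MT1X to -0.46 for MT1G, with a median of -0.93. Of the 6, 2 were at least 2-fold lower, MT1X and MT1E, the latter with a second probe set at -0.44; these near-identical copies can share hybridisation, so the 6 are not separate measurements. Of 28 histone genes, 22 lay below 0 with a median of -0.19 and 0 passed 2-fold, and the lowest was H2AC6 at -0.98. Many histone genes are also close copies. Each family median named here kept its sign under the 2 scalings that moved values, while 6 of the Frizzled receptors lay above 0 after quantile normalisation.

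Receptors and ligands of axon guidance differed gene by gene. Among 7 Eph receptors, EPHA1 was 4.12-fold and EPHB6 2.05-fold lower while EPHA2 was 2.01-fold higher (log2 difference 0.97 after quantile normalisation), and the median was -0.26 at percentile 0.56. Of 7 ephrins, EFNB2 was 4.89-fold higher and the median was -0.03 at percentile 39.3. Of 7 plexins, PLXNA2 was 6.77-fold higher and the median was 0.26 at percentile 99.0. Among 6 insulin-like growth factor binding proteins, IGFBP6 was 5.82-fold higher beside IGFBP3, IGFBP4 had a log2 difference of -0.71, and the median was 0.11 at percentile 85.0. None of 149 ZNF zinc finger genes, 20 protocadherins, 14 semaphorins and 17 genes with integrin symbols reached 2-fold. With 2.32% of all 9487 genes past 2-fold, 0 in the smaller of these families is near that share. The family medians were, in that order, -0.02, 0.06, -0.06 and 0.05, at percentiles 21.3, 89.8, 14.7 and 83.2. The 17 were matched by symbol and include the integrin-binding proteins ITGB3BP, ITGB1BP1 and ITGB1BP2, which are not integrins. A probe set annotated to LEFTY1 and LEFTY2 together went from 53 to 3960, so which of the pair was higher cannot be read from it.

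The first pattern is the lower pluripotency list. Swapped labels are argued against by CYP26A1, CRABP2 and RARB, higher with RA by 3.37, 3.55 and 2.04 on the log2 scale, though the mean over RARB probe sets was 0.95, and array scaling by the list median, which was -0.95 or lower under the 2 scalings that moved values. A uniform loss of undifferentiated cells would lower their genes by a common factor only if the remaining cells expressed none of them. Over the 12 members at 500 or more with DMSO, the log2 differences ran from -3.54 to 0.41. Their SD of 1.31 was 8.33 times that of 47 ribosomal and reference genes. The expression of these members in the remaining cells was not measured, so this spread cannot decide on such a loss. That loss and a mixture of cell states with different profiles stay open. So does any difference between the cultures other than RA, since 1 array stands for each.

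The second pattern is SKAP2, which in the reference gene order lies next to the HOXA cluster. A single faulty probe set is argued against by 2 further SKAP2 probe sets, at 21 and 26 with DMSO and 551 and 991 with RA, although the remaining one, alone in reaching 50 with DMSO, was near equal at 79 and 83. A rise of at least 2-fold shared by genes next to HOX clusters is argued against by the other 31 measured genes within 5 genes of the 4 clusters. Their median was 0.11 and 0 were at least 2-fold higher, with CREB5 highest (41 and 62) and NFE2L3 lowest at -1.29. That median was not placed among random lists, so a smaller shared change stays open. Most of the 31 genes lie beside clusters other than HOXA. Adjacent measured genes were both at least 2-fold higher in 6 pairs, among them NES with CRABP2 and SPRED2 with MEIS1, at the upper limit of the central 95% of 10000 random placements (0 to 6), which leaves such a tendency in general open, but none of the pairs holds SKAP2, whose nearest measured neighbours away from the cluster, SNX10, CBX3 and HNRNPA2B1, had log2 differences of -0.28, 0.03 and -0.12. A hypothesis specific to SKAP2, that it may share regulation with the HOXA genes beside it, was not tested and stays open, as HOXA2 was the only gene of that cluster measured at 50 or more.

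The third pattern is that genes known as feedback targets of FGF and ERK signalling moved apart. SPRY2, SPRY4 and ETV4 were at least 2-fold lower, or at -0.84, -0.97 and -0.84 with 50 added to each signal, with ETV5 at -0.96 and SPRY1 at -0.59, while DUSP6 and SPRED2 were at least 2-fold higher and DUSP4 had 0.46. For DUSP6 and SPRED2, disagreement between probe sets is argued against by their 5 probe sets at 50 or more, the lowest of which was at 1.18. SPRY1, SPRY2, SPRY4 and ETV4 had no second probe set, so this could not be checked for them. The 8 genes were picked after their values were seen, so their range of 3.44 on the log2 scale describes the pattern and tests no explanation of it. A candidate explanation that stays open is that RA or another input may act on DUSP6 and SPRED2 apart from the others, and it was not tested.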
